A study of Rattus norvegicus with 24 samples.

How the data were processed

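Total RNA had been taken from cortex and medulla of kidneys of Wistar rats aged 3 months, from sham rats and from rats killed 6, 24 or 120 h after bilateral ischemia of 20 min, per the labels. RNA was extracted with Trizol and RNeasy, treated with DNase, checked on an Agilent Bioanalyser and amplified into biotinylated cRNA with an Ambion kit, per the labels. Each of 8 groups had 3 arrays, 24 in all. No slide or scan date is given in the sources used here.

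The deposited intensity values, 1 per probe and array, are not normalized, per the file headers, and ranged from 28.5 to 36007.6. The scanner software is not given in the sources used here. Beside each intensity the authors deposited a detection value, a fraction between 0 and 1. Its column is headed as a p-value, but it rose with intensity (Spearman correlation 0.921 across probes) in 825 steps, so a detection p was taken as 1 minus that fraction. The deposited series table holds log2 values made by the authors by a method not given in the sources used here. Its columns share the same sorted values to within 0.0102, each has a median of 6.72, and each correlates best with its own array (r of 0.990 or more). The log2 scale was read from the values, which are not centred on 0, and the shared sorted values are those that quantile normalization leaves, while any background correction stays unstated. No 2 arrays held identical values, and array signal over background limits what could be measured.

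Normalization used neqc of limma 3.58.1 in R 4.3.3, which corrects background by normexp from the detection p, adds an offset of 16, quantile-normalizes and takes log2. Probes with a detection p under 0.05 on at least 3 arrays were kept, 14390 of 22523. Probe annotation gave 1 gene symbol for 13793 probes (13337 symbols) and none for 8730. Of the gene identifiers 41 were not in the reference table, and 0 symbols changed on updating. No probe was paired there with Fga or with the injury gene Havcr1.

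One linear model with 8 group means was fitted to all arrays with lmFit and eBayes, with 16 residual and 3.34 prior degrees of freedom, so that all groups share 1 estimate of the spread. The 14 comparisons were each time against sham within each region, sham medulla against sham cortex, the difference between the regional responses at each time, and 24 against 6 h and 120 against 24 h within each region. P-values were adjusted within a comparison by Benjamini-Hochberg, with a threshold of 0.05. Where a group had no array above background, only a bound on the fold was given, or a value named as fitted. Such bounds hold for the neqc values only. A check added after the data were seen found Spp1 or Clu within 0.5 of the top of the normalized scale (14.775) in an injured group behind 11 of 225 named gene calls, where differences are compressed. An exact test of 3 against 3 arrays cannot give a p under 0.1, which is why the model's adjusted p is reported.

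Gene lists were fixed before the data were examined and tested on 9799 genes, 1 probe per gene with the highest mean. They were fibrinogen chains, kidney injury, coagulation, acute phase, immediate early, heat shock, oxidative stress, endoplasmic reticulum stress, p53 targets, cell cycle, chemokines, macrophage, neutrophil, lymphocyte, endothelial, glomerular, proximal tubule, thick ascending limb, distal tubule, collecting duct, medullary osmotic, fatty acid oxidation, glycolysis, oxidative phosphorylation, extracellular matrix, complement, interferon, MHC class II, cholesterol, erythrocyte, urothelium, adrenal and adipocyte genes. Each of the 33 lists was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which asks only whether a list's genes moved one way on balance. Of 138 camera calls over the 14 comparisons, 5 held with the estimated correlation. Lists of liver and platelet genes were added later for the question of RNA from other sources.

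Named genes followed a rule fixed at the same time. In comparisons with sham and between the sham regions they were the 10 highest and 10 lowest changes among probes past the threshold whose 3 arrays lay beyond the 3 reference arrays. In the other comparisons 5 per side were taken. Symbols that stand for uncharacterised loci were passed over, and each gene had 1 probe. Fga, Fgb, Fgg, Havcr1, Lcn2, Spp1, Clu, Timp1, Vim, Umod, Slc34a1 and Aqp2 were always named where measured, with up to 4 called members per list.

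Alternatives were normexp with an offset of 50 and quantile normalization, quantile normalization alone, the authors' series values, median scaling, no filter on dim probes, a strict filter (detection p under 0.01 on all 3 arrays of a group), 1 probe per gene, only the groups compared, only the 12 arrays of a region, array weights, eBayes with trend and robust settings, an adjusted p under 0.01, a change of at least 2-fold, a replicate block, animal as a random block, and each array left out in turn. A distal tubule covariate and list counts without the library labelled sham medulla replicate 1 were added after the data were seen. For the animal block, cortex and medulla of the same time and replicate number were taken to come from the same animal, which the labels do not state. The slide could not be used as a block. The fitting was tested on simulated data for cortex at 24 h with 14390 probes, of which 200 were changed, and recovered 12.5% of 1.5-fold, 59% of 2-fold and 93% of 4-fold changes, with 2, 3 and 5 false calls. The simulated noise was independent between probes and arrays. It therefore does not show how many false calls arise from differences that many probes of an array share. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.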

Results

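Rat kidneys injured by ischemia and reperfusion were compared with kidneys of sham rats, and the series title poses the question of fibrinogen in the damaged kidney. Blood flow to both kidneys of Wistar rats had been interrupted for 20 min, and cortex and medulla were taken 6, 24 or 120 h after it returned. RNA of each region was hybridised to Illumina bead arrays, with 3 arrays in each of 8 groups and 24 arrays in all. Median intensity per array lay between 67.3 and 98.1, and 11173 to 12710 of 22523 probes (49.6% to 56.4%) were above background. Changes below are log2 differences between group means, ± SE where given, with n = 3 arrays per group, and the number of arrays limits their precision. The labels do not say whether the replicates of a group were separate animals, so the p-values measure the spread between these samples, which may be technical.

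Fibrinogen, the soluble precursor of fibrin, was measured through its beta and gamma chains, Fgb and Fgg; no probe was paired with the alpha chain Fga in the annotation used here. In sham kidneys both transcripts lay near background: Fgb and Fgg were each detected on 1 of 3 sham cortex arrays, and on 0 and 1 of 3 sham medulla arrays, whereas all 18 arrays of injured tissue detected both. In cortex Fgb rose by 2.80 ± 0.60 at 6 h, 6.01 ± 0.60 at 24 h and 3.47 ± 0.60 at 120 h (adjusted p = 0.00334, 1.65e-06 and 0.00191). Its mean normalized intensity went from 4.86 ± 0.18 (log2, SD) in sham cortex to 10.86 ± 1.18 at 24 h, a 64.2-fold difference. Fgg rose in cortex by 4.98 ± 0.65 at 24 h (31.6-fold, adjusted p = 2.79e-05) and by 2.39 ± 0.65 at 120 h (adjusted p = 0.037). At 6 h its difference of 1.74 ± 0.65 did not pass over all probes (adjusted p = 0.0683) and passed adjusted over the list alone (0.0153). The chains were listed because the series title names fibrinogen, a choice that may rest on these same arrays. Adjustment over this list alone, here and below, does not count that choice. In medulla, where no sham array detected Fgb, only a bound could be given: the injured group's mean was set against the sham mean of, per array, the higher of the lowest signal among detected probes and the probe's own. Fgb was at least 7.43-fold, 10.3-fold and 11.2-fold higher than sham at 6, 24 and 120 h (adjusted p = 0.00084, 0.000292 and 0.000974), and Fgg rose by 2.11, 2.44 and 2.31 (adjusted p = 0.0177, 0.0079 and 0.0243). The only sham medulla array that detected Fgg was replicate 1, a library that resembled sham cortex, as described below. Without it no sham medulla array detected Fgg, so its medulla differences are fitted values near background. From 6 to 24 h both chains rose further in cortex, Fgb by 3.20 and Fgg by 3.25 (adjusted p = 0.0051 and 0.00955). From 24 to 120 h they fell by 2.54 and 2.59 there (adjusted p = 0.0297 and 0.0407). In medulla the steps between times were 0.47 and 0.33, then 0.12 and -0.13, and did not pass. The 24 h responses of medulla and cortex differed by -2.54 ± 0.92 for Fgg, which did not pass over all probes (adjusted p = 0.295) and passed adjusted over the list alone (0.0126). For Fgb no such difference is given, since its level in sham medulla was not above background. That of Fgg was above it there on replicate 1 alone.

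The size of the fold depended on the background correction and its offset. With quantile normalization alone Fgb in cortex differed from sham by 1.82, 4.70 and 2.35 at 6, 24 and 120 h and Fgg at 24 h by 3.71, and with the authors' series values by 1.46, 4.20, 1.94 and 3.21. The bounds for Fgb in medulla hold for the neqc values only: the fitted log2 differences there were 2.015, 2.42 and 2.496 with quantile normalization alone, 2.03, 2.44 and 2.51 with normexp at an offset of 50 and 1.61, 1.98 and 2.03 with the series values, all under those bounds. Without 24 h cortex replicate 3 the Fgb difference at 24 h was 5.36, without 24 h cortex replicate 1 that of Fgg was 5.63, and without 6 h cortex replicate 1 that of Fgb at 6 h was 3.41. Without 120 h cortex replicate 1 the Fgg difference at 120 h was 3.05, and without 24 h medulla replicate 1 the fitted Fgb difference there was 4.16 instead of 3.56. The fall of Fgb in cortex from 24 to 120 h lost its call without 24 h replicates 2 or 3 or 120 h replicates 1 or 3 (differences of -2.68, -1.89, -2.12 and -2.54, with adjusted p from 0.00575 to 0.139 over its alternatives). That of Fgg did so without the same arrays (-2.44, -2.098, -1.93 and -2.68; 0.014 to 0.172 over its alternatives). The Fgg rise from 6 to 24 h lost its call without 6 h replicate 1 or 24 h replicate 3 (2.68 and 2.75; 0.00343 to 0.176 over its alternatives), and was 3.89 without 24 h replicate 1. That of Fgb was 2.60 and 2.56 without 6 h replicate 1 and 24 h replicate 3 and kept its call, and the Fgg fall was -3.24 without 24 h replicate 1. With only the groups compared, all 4 of these calls ended, with only the 12 arrays of the region all but the Fgb rise, and without a filter on dim probes both falls.

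As a list of 2 the chains passed camera in cortex at 24 and 120 h and in medulla at 120 h (adjusted p = 0.00333, 0.00276 and 0.01), with adjusted p = 0.3, 0.124 and 0.184 with an estimated correlation. With the mean of distal tubule markers on each array as a covariate, chosen after the data were seen, Fgb no longer passed in medulla at 6, 24 and 120 h (adjusted p = 0.074, 0.185 and 0.0867, each the highest over its alternatives). Its fitted differences, no sizes, went from 3.08, 3.56 and 3.68 (SE 0.60 each) to 2.84, 3.23 and 3.43 with SE of 0.91, 1.08 and 0.92, so the calls ended with the larger standard errors. The Fgg call in cortex at 120 h ended without sham cortex replicates 1, 2 or 3 or 120 h cortex replicates 2 or 3 (adjusted p = 0.103, 0.0856, 0.0827, 0.209 and 0.0884; 0.00384 to 0.209 over its alternatives). In medulla the Fgg call ended at 6 h without replicate 1 of that group (0.101; 0.00142 to 0.23 over its alternatives), at 24 h with the authors' series values (0.0516) and the distal tubule covariate (0.398, with 2.36 and an SE of 1.17 against 2.44 and 0.65; 0.000566 to 0.398 over its alternatives), and at 120 h without sham medulla replicates 1, 2 or 3 or 120 h replicates 1 or 2 (0.0567, 0.0557, 0.0611, 0.0875 and 0.0645; 0.00493 to 0.304 over its alternatives). Without 6 h cortex replicate 1 the Fgg difference in cortex at 6 h passed (0.0318; 0.0318 to 0.24 over its alternatives).

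**Figure D1:**
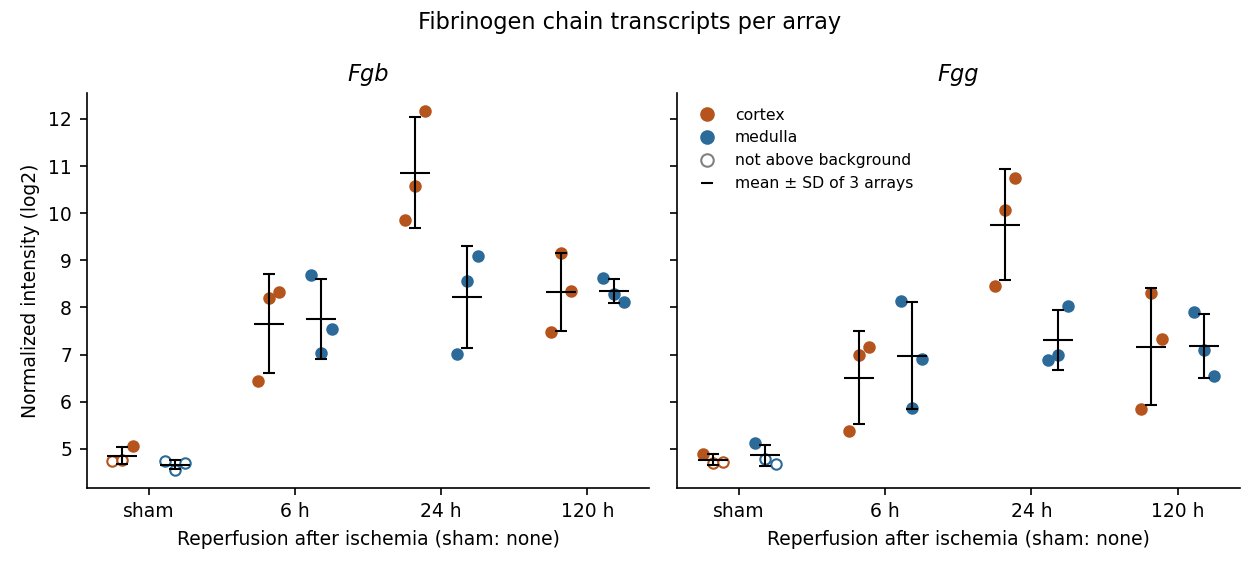
Normalized intensity (log2, vertical axis) of Fgb and Fgg on each array by reperfusion time (horizontal axis) in cortex and medulla; bars are mean ± SD of 3 arrays and open circles are arrays not above background. The 3 cortex arrays at 24 h had a mean of 10.86 for Fgb, against 4.86 in sham cortex.

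**Figure D2:**
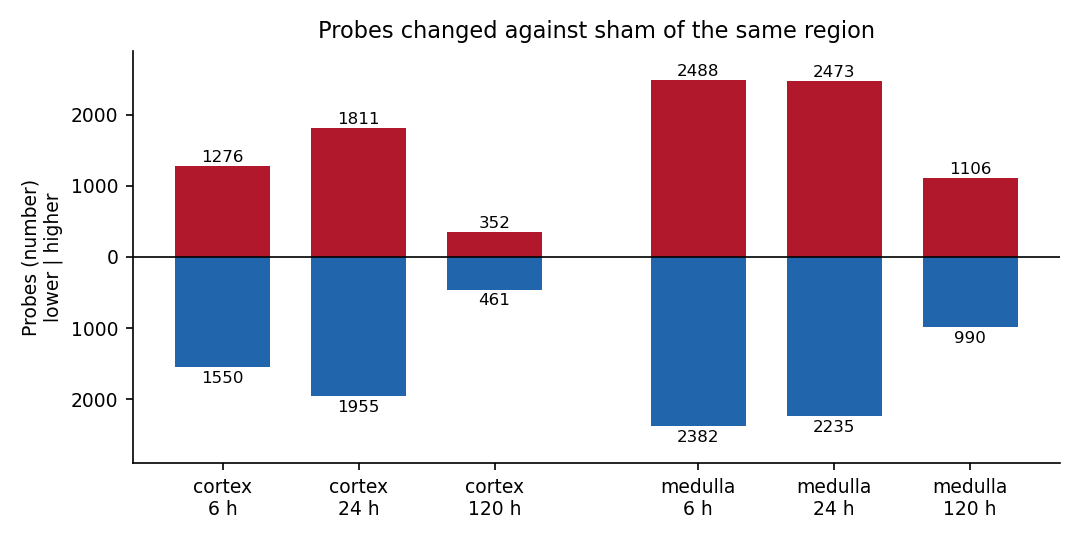
Number of probes (vertical axis) higher or lower than sham of the same region at an adjusted p under 0.05, by region and reperfusion time (horizontal axis). The medulla at 6 h had 2488 probes higher and 2382 lower, the cortex at 120 h had 352 and 461.

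At 6 h the cortex showed higher tubular injury genes, chemokines, immediate early genes and stress genes. Akr1b8, an aldo-keto reductase, rose by 3.97 ± 0.48, the TWEAK receptor Tnfrsf12a by 3.84 ± 0.55, the efflux pump Abcb1b by 3.40 ± 0.42 and the small heat shock protein Cryab by 3.05 ± 0.38. Gatm, which makes the precursor of creatine, fell by 3.42 ± 0.62, and the creatine transporter Slc16a12 fell by 3.36 ± 0.31. Mapk4 fell by 3.28, the retinoid X receptor Rxrg by 3.15, Klhl25 by 2.98, Gna12 by 2.93, Nrep by 2.89, Slc22a23 and Slc43a2 by 2.87 each, and the lactate cotransporter Slc5a12 by 2.86. Fam25a (3.92), Lxn (3.07) and Hsd3b1 (3.03) were also among the largest rises. Of the always named genes, Spp1 (2.23), the secreted chaperone Clu (1.26) and Timp1 (2.72) rose, while Vim (0.69), Umod (0.17), Slc34a1 (-1.16) and Aqp2 (-0.86) did not pass.

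Of 22 measured kidney injury genes, 11 rose in cortex at 6 h (14 adjusted over the list alone), among them Pvr (3.36), the iron-siderophore binder Lcn2 (2.84), Timp1 and the keratin Krt20 (at least 5.07-fold); camera adjusted p = 1.17e-05, and adjusted p = 0.271 with an estimated correlation. Immediate early genes rose with 8 of 19 members (11 adjusted over the list alone), led by Atf3 (2.89), Klf6 (2.02) and Ier2 (1.77). Immediate early genes passed camera with adjusted p = 4.59e-05, and 0.484 with an estimated correlation. Chemokine, cytokine and adhesion genes rose with 10 of 27 members (10 adjusted over the list alone, with 1 lower), such as Cxcl10 (3.55), Ccl20 (3.42) and Icam1 (1.53). Chemokine genes passed camera with adjusted p = 0.000653, and adjusted p = 0.271 with an estimated correlation. Oxidative stress genes rose with 5 of 17 members and 1 fell (6 and 1 adjusted over the list alone), with the heme oxygenase Hmox1 (2.73), Gpx2 (2.67) and Nqo1 (2.52) highest. Oxidative stress genes passed camera with adjusted p = 0.0134, and adjusted p = 0.173 with an estimated correlation. Endoplasmic reticulum stress genes rose with 7 of 20 members (7 adjusted over the list alone), such as Ppp1r15a (1.53) and Ddit3 (1.36). These stress genes passed camera with adjusted p = 0.00968, and adjusted p = 0.484 with an estimated correlation. Among neutrophil markers 3 of 7 rose (3 adjusted over the list alone): Lcn2, which injured tubules also make, S100a8 (2.56) and Il1r2 (1.32). Neutrophil markers passed camera with adjusted p = 0.0173, and adjusted p = 0.173 with an estimated correlation. The proximal tubule list was lower (5 of 40 fell and 1 rose, 4 and 1 adjusted over the list alone; median -0.33, adjusted p = 0.025, and adjusted p = 0.744 with an estimated correlation), led by Gatm, Slc5a12 and Acmsd (-2.78), while the vitamin D hydroxylase Cyp24a1 rose (2.37). The cell cycle list had 4 of 35 members higher (Prc1, Ccnb2, Cdk1 and Cdc20, each of which missed the threshold when adjusted over the list alone), with a median of 0.49. Cell cycle genes passed camera with adjusted p = 0.0138, and adjusted p = 0.717 with an estimated correlation.

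In cortex at 6 h limma called 2826 of 14390 probes, 1276 higher and 1550 lower. The count was 1609 without sham cortex replicate 1 and 1253 without 6 h cortex replicate 2.

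At 24 h the cortex was marked by fibrinogen and by genes of mitosis. Cdk1, the kinase that drives entry into mitosis, rose by 5.28 ± 0.37, the spindle protein Prc1 by 4.84 ± 0.43, the cyclin Ccnb2 by 4.74 ± 0.45, the kinesin Kif22 by 4.32 ± 0.39 and the spindle protein Knstrn by 4.18 ± 0.36. Lcn2 (4.33), Cyp3a9 (4.27), Timp1 (4.12), Clu (3.79), Spp1 (3.26) and the intermediate filament gene Vim (1.08) rose as well. Gatm fell by 4.45 ± 0.62, the carbonic anhydrase Car12 by 3.47 ± 0.39, Slc16a12 by 3.42 ± 0.31, the mitochondrial dehydrogenase subunit Dhtkd1 by 3.39, Klhl25 by 3.23, the methionine adenosyltransferase Mat2a by 3.17, Mapk4 by 3.15, Gna12 by 3.13 and Slc43a2 by 3.04; Lzts3 was at least 9.02-fold lower. Umod (-0.87), Slc34a1 (-1.29) and Aqp2 (-1.20) did not pass.

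Of 35 measured cell cycle genes, 31 rose in cortex at 24 h (32 adjusted over the list alone), with a median of 2.24, or 2.06 with genes that had no signal in 1 group set at their bound, 1.35 with quantile normalization alone and 1.24 with the authors' series values. Cell cycle genes passed camera with adjusted p = 6.23e-25, and adjusted p = 0.221 with an estimated correlation. Kidney injury genes rose with 12 of 22 members (12 adjusted over the list alone). Injury genes passed camera with adjusted p = 5.61e-06, and adjusted p = 0.3 with an estimated correlation. Complement genes rose with 7 of 16 members (8 adjusted over the list alone), among them C4b (2.28), Cfi (2.27), C2 (1.94) and C1qa (1.56). Complement genes passed camera with adjusted p = 0.00333, and adjusted p = 0.384 with an estimated correlation. Monocyte and macrophage markers rose with 8 of 22 members (9 adjusted over the list alone), such as Cd14 (1.65) and Aif1 (1.54). Macrophage markers passed camera with adjusted p = 0.0075, and adjusted p = 0.681 with an estimated correlation. Extracellular matrix genes rose with 8 of 27 members and 1 fell (9 and 1 adjusted over the list alone), led by the collagen Col1a1 (2.14) and fibronectin Fn1 (1.70). Matrix genes passed camera with adjusted p = 0.0346, and adjusted p = 0.681 with an estimated correlation. Chemokine genes had 9 members higher and 1 lower, with the same numbers adjusted over the list alone (Ccl20 3.63, Tnfrsf12a 3.61, Cxcl10 2.50). Chemokine genes passed camera with adjusted p = 0.00252, and adjusted p = 0.384 with an estimated correlation. The acute phase list without fibrinogen had 4 of 18 members higher (4 adjusted over the list alone), namely Serpina3n (3.45), the heme-binding hemopexin gene Hpx (3.01), the lipopolysaccharide-binding protein gene Lbp (2.35) and Stat3 (0.94), with a list test that did not pass (adjusted p = 0.0682). The proximal tubule list was lower with a median of -0.65 (4 of 40 fell and 1 rose, 4 and 1 adjusted over the list alone; adjusted p = 0.00653, and adjusted p = 0.681 with an estimated correlation). Immediate early genes (5 of 19 higher, 5 adjusted over the list alone; adjusted p = 0.0346) and endoplasmic reticulum stress genes (3 of 20 higher, 3 adjusted over the list alone; adjusted p = 0.0369) passed too, with adjusted p = 0.681 and 0.644 with an estimated correlation. The oxidative stress list had a median of -0.001 but a mean of 0.43 and did not pass (adjusted p = 0.352), with Gpx2 at 3.38 and 5 of 17 members higher and 2 lower (7 and 2 adjusted over the list alone).

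In cortex at 24 h 3766 probes passed, 1811 higher and 1955 lower, while median scaling gave 2134 and 1606 and 1 probe per gene 1376 and 1314, so the balance turned.

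At 120 h the cortex retained high injury genes beside macrophage, lymphocyte, antigen presentation and matrix genes. Lcn2 rose by 4.31 ± 0.54, Clu by 3.37 ± 0.37, Spp1 by 3.06 ± 0.22, Cdk1 by 3.27 ± 0.37 and the phosphate cotransporter Slc34a2 by 3.09 ± 0.75. Ugt2b7 (3.18), Cxcl10 (2.96), Tnfrsf12a (2.91) and Ccnb2 (2.91) were the other genes among the 10 largest rises beside Fgb. Mapk4 fell by 2.52 ± 0.41, Slc16a12 by 2.50, Acmsd of the NAD synthesis pathway by 2.40, Tmem86a by 2.38, the potassium channel Kcnj15 by 2.34, Ggta1 and Slc22a23 by 2.20 each, the monoamine oxidase Maob by 2.17, Nek7 by 2.07 and Sh3bgrl2 by 2.05. Timp1 (2.51), Vim (0.97), Umod (0.14), Slc34a1 (-0.33) and Aqp2 (0.60) did not pass.

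Of 9 measured MHC class II genes, 5 rose in cortex at 120 h (8 adjusted over the list alone), among them RT1-Db1 (1.69), the invariant chain Cd74 (1.46) and RT1-DMa (1.23); adjusted p = 1.49e-07, and this was the only list called in a comparison with sham that held with an estimated correlation (adjusted p = 0.0339). Monocyte and macrophage markers rose with 6 of 22 members (12 adjusted over the list alone), such as C1qa (2.04) and C1qc (1.84). Macrophage markers passed camera with adjusted p = 6.21e-10, and adjusted p = 0.12 with an estimated correlation. Lymphocyte markers rose with 5 of 16 members (8 adjusted over the list alone), such as Cd3g (1.41) and Nkg7 (1.21). Lymphocyte markers passed camera with adjusted p = 1.11e-05, and adjusted p = 0.185 with an estimated correlation. Kidney injury genes had 7 of 22 members higher (10 adjusted over the list alone; adjusted p = 2.45e-09, and adjusted p = 0.0887 with an estimated correlation) and chemokine genes 7 of 27 (10 adjusted over the list alone; adjusted p = 1.39e-07, and adjusted p = 0.0772 with an estimated correlation). Extracellular matrix genes rose with 4 of 27 members (13 adjusted over the list alone), led by Col1a1 (2.29). Matrix genes passed camera with adjusted p = 3.09e-07, and adjusted p = 0.208 with an estimated correlation. Complement genes rose with 6 of 16 members and 1 fell (8 and 1 adjusted over the list alone), with C2 (2.76) and Cfi (2.62) highest. Complement genes passed camera with adjusted p = 3.19e-06, and adjusted p = 0.12 with an estimated correlation. Cell cycle genes had 13 of 35 members higher (17 adjusted over the list alone, with 1 lower), with a median of 0.59, or 0.37 at the bounds. Cell cycle genes passed camera with adjusted p = 1.84e-10, and adjusted p = 0.203 with an estimated correlation. Acute phase genes without fibrinogen rose with 2 of 18 members (4 adjusted over the list alone), Serpina3n (2.24) and Stat3 (0.93). Acute phase genes passed camera with adjusted p = 0.0066, and adjusted p = 0.12 with an estimated correlation.

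In cortex at 120 h 813 probes passed, 352 higher and 461 lower, while median scaling gave 349 and 317 and 1 probe per gene 317 and 310, so the balance turned. The count was 322 without sham cortex replicate 1 and 297 without 120 h cortex replicate 2.

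Before the medulla was compared over time, the sham regions were compared with each other. Sham medulla was higher than sham cortex for genes of fat cells and osmolyte handling, namely Thrsp (3.73 ± 0.78), Fabp4 (3.62 ± 0.69), Car3 (3.34 ± 0.65), the adipsin gene Cfd (2.98 ± 0.66) and the inositol transporter Slc5a3 (2.10), and for Cryab (2.64), Nupr1 (2.58), Ppp1r1b (2.53), Ndrg4 (2.49), Smoc2 (2.39), Spink8 (2.13) and Spp1 (2.00). It was lower for the pendrin gene Slc26a4 (-2.68 ± 0.53), Folh1 (-2.49), the distal tubule calcium binder Calb1 (-2.47 ± 0.46), Dusp15 (-2.32), Sfrp2 (-2.29), Hmx2 (-2.28), the coagulation factor gene F13b (-2.28), Slc16a6 (-2.23), the podocyte gene Nphs1 (-2.19 ± 0.45) and Slc22a23 (-2.16). Of 7 adipocyte markers 2 were higher (6 adjusted over the list alone), with a median of 2.06, or 1.34 with quantile normalization alone and 1.095 with the series values. Adipocyte markers passed camera with adjusted p = 2.82e-08, and adjusted p = 0.128 with an estimated correlation. Of 10 distal convoluted and connecting tubule markers 1 was lower (6 adjusted over the list alone), with a median of -1.34 (adjusted p = 2.13e-05, and adjusted p = 0.128 with an estimated correlation), and of 11 glomerular markers 2 were lower (6 adjusted over the list alone; adjusted p = 0.000516, and adjusted p = 0.185 with an estimated correlation). Proximal tubule genes had a median of -0.76, with 1 of 40 lower (14 adjusted over the list alone). Proximal tubule genes passed camera with adjusted p = 2.45e-06, and adjusted p = 0.453 with an estimated correlation. Medullary osmotic genes had 1 of 11 higher (3 adjusted over the list alone; adjusted p = 0.00247, and adjusted p = 0.243 with an estimated correlation), and thick ascending limb markers had a median of 0.77 with 3 of 12 higher adjusted over the list alone (adjusted p = 0.00115, and adjusted p = 0.291 with an estimated correlation). Lists of injury, immediate early, interferon, complement and matrix genes were higher in sham medulla too, the group its injured arrays were compared with. Of 22 kidney injury genes 1 was higher, Spp1 (1 adjusted over the list alone), with a median of 0.436 (adjusted p = 3.24e-05, and adjusted p = 0.284 with an estimated correlation). Of 19 immediate early genes 0 were higher by limma (2 adjusted over the list alone), with a median of 0.591 (adjusted p = 0.000516, and adjusted p = 0.453 with an estimated correlation). Interferon genes had a median of 0.381 (adjusted p = 0.00182, and adjusted p = 0.453 with an estimated correlation), complement genes one of 0.464 (adjusted p = 0.00211, and adjusted p = 0.409 with an estimated correlation) and matrix genes one of 0.201 (adjusted p = 0.015, and adjusted p = 0.658 with an estimated correlation).

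The comparison of the sham regions gave 200 probes, 63 higher and 137 lower in medulla. The library labelled sham medulla replicate 1 correlated more closely with the sham cortex arrays (mean r across probes = 0.979) than with its own group (0.968), and without it the count was 798. Leaving out sham medulla replicates 2 or 3 gave 21 or 77 probes, and leaving out sham cortex replicates 2 or 3 gave 30 or 56.

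**Figure D3:**
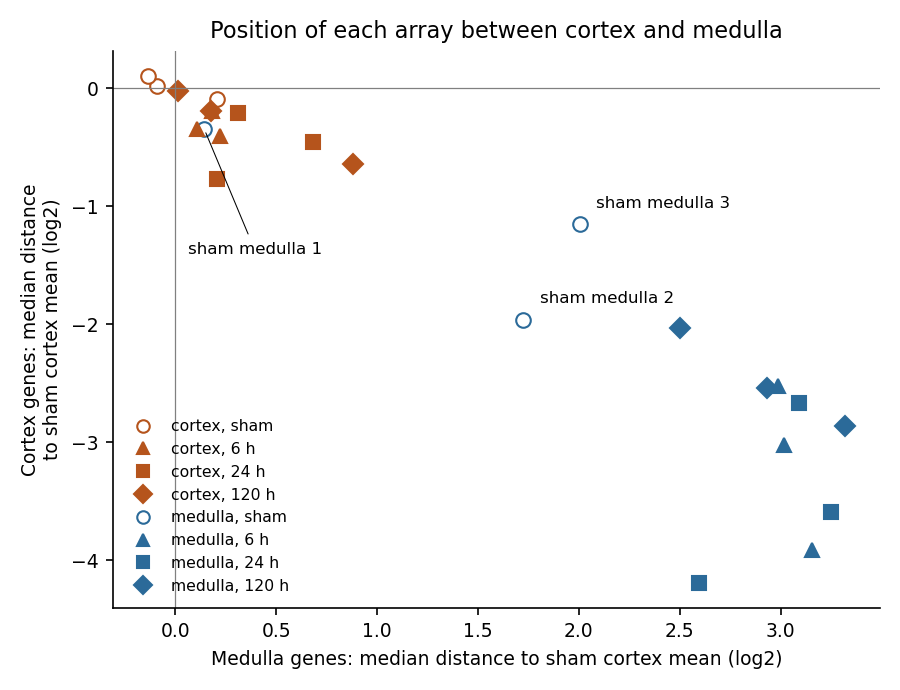
Median distance of each array to the sham cortex mean (log2) for 87 genes higher in injured medulla (horizontal axis) and 207 genes higher in injured cortex (vertical axis), with gene sets taken from injured arrays only. The library labelled sham medulla replicate 1 lies at 0.14 and -0.34, the other sham medulla arrays lie at 1.72 and -1.96 and at 2.00 and -1.15.

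At 6 h the medulla showed a broad rise of chemokine, interferon, injury and macrophage genes and lower levels of most of the proximal tubule list. Glycam1, a mucin-like ligand of L-selectin, rose by 5.36 ± 0.51, Cxcl10 by 4.50 ± 0.74, Timp1 by 4.49 ± 0.79, Lcn2 by 3.94 ± 0.54, Rnd1 by 3.87, Spock2 by 3.76, Cxcl11 by 3.70, Csrp3 by 3.65, A3galt2 by 3.59 and Cdhr1 by 3.45. Clu (2.20), Vim (1.39) and Spp1 (1.22) rose as well, while Umod (-0.29) and Aqp2 (0.23) did not pass. Gatm fell by 5.28 ± 0.62, the cytochrome Cyp2e1 by 4.51 ± 0.57, the glucose cotransporter Slc5a2 by 4.27 ± 0.68, the phosphate cotransporter Slc34a1 by 4.03 ± 0.68, Spink1l by 4.03, Slco4c1 by 3.98, Ppm1k by 3.95 and Dhtkd1 by 3.85; Slc5a12 and Cacng5 were at least 10.98-fold and 10.7-fold lower.

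Of 40 measured proximal tubule genes, 32 fell in medulla at 6 h (35 adjusted over the list alone), with a median of -2.58. Proximal tubule genes passed camera with adjusted p = 1.06e-15, and adjusted p = 0.293 with an estimated correlation. Distal convoluted and connecting tubule markers, which are cortical, had 4 of 10 members lower (4 adjusted over the list alone), Klk1 (-2.75), Slc12a3 (-2.73), Calb1 (-2.57) and Wnk1 (-1.65), with a median of -0.64. Distal tubule markers passed camera with adjusted p = 0.0378, and adjusted p = 0.461 with an estimated correlation. Fatty acid oxidation genes fell with 14 of 27 members (16 lower and 1 higher adjusted over the list alone), such as Acsm2 (-2.88). Fatty acid oxidation genes passed camera with adjusted p = 0.000104, and adjusted p = 0.521 with an estimated correlation. Kidney injury genes had 15 of 22 members higher (15 adjusted over the list alone; adjusted p = 1.15e-05, and adjusted p = 0.293 with an estimated correlation). Chemokine genes had 15 of 27 higher and 2 lower (18 and 2 adjusted over the list alone), such as Icam1 (2.43). Chemokine genes passed camera with adjusted p = 3.2e-05, and adjusted p = 0.293 with an estimated correlation. Interferon response genes rose with 14 of 20 members (14 adjusted over the list alone), such as Oasl (2.64), Irf1 (2.15) and Ifit3 (1.95). Interferon genes passed camera with adjusted p = 6.19e-05, and adjusted p = 0.443 with an estimated correlation. Macrophage markers rose with 13 of 22 (13 adjusted over the list alone), such as Cd14 (2.67) and C1qb (2.49). Macrophage markers passed camera with adjusted p = 0.000135, and adjusted p = 0.461 with an estimated correlation. Immediate early genes rose with 12 of 19 (12 adjusted over the list alone), such as Fos (2.50). Immediate early genes passed camera with adjusted p = 0.000135, and adjusted p = 0.461 with an estimated correlation. Acute phase genes without fibrinogen rose with 9 of 18 and 1 fell (10 and 1 adjusted over the list alone), with Serpina3n at 3.39 and Apcs at -3.37. Acute phase genes passed camera with adjusted p = 0.0258, and adjusted p = 0.293 with an estimated correlation. The coagulation list without fibrinogen moved both ways, with 8 of 22 higher and 6 lower (8 and 6 adjusted over the list alone), and its test did not pass (adjusted p = 0.851). Its lower members were the thrombin gene F2 (-2.69), the plasmin inhibitor gene Serpinf2 (-2.50), the antithrombin gene Serpinc1 (-2.24), Vwf (-1.91), Tfpi (-0.58) and F13b (at least 2.98-fold). Higher members included the factor V gene F5 (1.70), the protein C receptor gene Procr (1.60) and the thrombin receptor gene F2r (1.47), with a list median of -0.04, a mean of -0.17 and a positive fry direction.

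In medulla at 6 h 4870 probes passed, 2488 higher and 2382 lower. Without the library labelled sham medulla replicate 1 the count was 3605, with 28 proximal tubule genes, 3 distal tubule markers and 13 fatty acid oxidation genes lower, and 8 interferon, 9 macrophage, 14 injury and 15 chemokine genes higher. With the mean of the distal tubule markers on each array as a covariate, chosen after the data were seen, it was 736, with 2 proximal tubule genes lower.

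At 24 h the medulla combined higher mitotic and interferon genes with lower proximal and distal convoluted tubule genes. Ccnb2 rose by 4.64 ± 0.45, Prc1 by 4.54 ± 0.43, Cdk1 by 4.49 ± 0.37, Glycam1 by 4.47 ± 0.51, Lcn2 by 4.26 ± 0.54, the ribonucleotide reductase subunit Rrm2 by 4.12 ± 0.36, Kif22 by 3.94 and Cxcl10 by 3.86; the mitotic kinase gene Aurkb was at least 15.2-fold and Knstrn at least 12.3-fold higher. Timp1 (3.77), Clu (3.22), Vim (1.55) and Spp1 (1.29) rose, and Umod (-0.59) and Aqp2 (0.76) did not pass. Gatm fell by 5.71 ± 0.62, Ugt2b35 by 5.55 ± 0.61, Cyp2e1 by 5.26 ± 0.57, the olfactory receptor gene Or2n1e by 5.13, the kallikrein Klk1 by 4.62, Spink1l by 4.44, Slc34a1 by 4.24, the organic anion transporter Slc22a6 by 4.21 and Slc5a2 by 3.97; Klk1b3 was at least 15.6-fold lower.

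Of 35 cell cycle genes, 30 rose in medulla at 24 h (30 adjusted over the list alone), with a median of 1.98, or 1.39 with quantile normalization alone and 1.08 with the series values. Cell cycle genes passed camera with adjusted p = 1.77e-18, and adjusted p = 0.34 with an estimated correlation. Proximal tubule genes fell with 35 of 40 members (37 adjusted over the list alone), with a median of -3.05. Proximal tubule genes passed camera with adjusted p = 7.96e-19, and adjusted p = 0.34 with an estimated correlation. Distal tubule markers fell with 5 of 10 members (5 adjusted over the list alone), with a median of -1.31 and Slc12a3 at -3.12. Distal tubule markers passed camera with adjusted p = 0.0107, and adjusted p = 0.34 with an estimated correlation. Interferon genes rose with 14 of 20 members (15 adjusted over the list alone), such as Oasl (2.77) and Mx1 (2.62). Interferon genes passed camera with adjusted p = 2.15e-06, and adjusted p = 0.34 with an estimated correlation. Macrophage markers had 15 of 22 members higher (16 adjusted over the list alone; adjusted p = 2.15e-05, and adjusted p = 0.371 with an estimated correlation) and chemokine genes 11 of 27 with 2 lower (12 and 2 adjusted over the list alone; adjusted p = 0.0015, and adjusted p = 0.34 with an estimated correlation). Kidney injury genes had 14 of 22 higher (14 adjusted over the list alone, with 1 lower). Injury genes passed camera with adjusted p = 0.000146, and adjusted p = 0.34 with an estimated correlation. Extracellular matrix genes had 11 of 27 higher and 2 lower (12 and 2 adjusted over the list alone), such as Bgn (2.23) and Tgfbi (-1.84). Matrix genes passed camera with adjusted p = 0.0272, and adjusted p = 0.716 with an estimated correlation. MHC class II genes had 5 of 9 higher (5 adjusted over the list alone; adjusted p = 0.0159, and adjusted p = 0.34 with an estimated correlation). Fatty acid oxidation genes fell with 13 of 27 members and 1 rose (13 and 2 adjusted over the list alone). Fatty acid oxidation genes passed camera with adjusted p = 0.000324, and adjusted p = 0.617 with an estimated correlation.

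In medulla at 24 h 4708 probes passed, 2473 higher and 2235 lower, and median scaling gave 2885 and 1800. Without the library labelled sham medulla replicate 1 the count was 3167, with 32 proximal tubule genes, 5 distal tubule markers and 11 fatty acid oxidation genes lower, and 28 cell cycle, 14 interferon, 11 macrophage and 10 injury genes higher. With the distal tubule covariate it was 86, with 9 cell cycle genes higher.

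At 120 h the medulla was high in matrix, macrophage, interferon, complement and injury genes. Lcn2 rose by 4.37 ± 0.54, the protease inhibitor gene A2m by 4.0 ± 0.72, Serinc2 by 3.40 ± 0.55, Clu by 3.39 ± 0.37, Spock2 by 3.25, the cilium gene Tekt1 by 3.22, complement factor Cfb by 3.21, Serpina3n by 3.18 and Ccnb2 by 3.17. Timp1 (2.91), the water channel gene Aqp2 (2.28 ± 0.71), Vim (1.32) and Spp1 (1.16) rose, and Umod (-0.07) and Slc34a1 (-1.24) did not pass. Cyp2c11 fell by 3.66 ± 1.11, Cacng5 by 3.52, Slc5a12 by 3.28, Slco4c1 and the phosphate cotransporter Slc34a3 by 3.20 each, Adh1c by 3.09, Slc5a2 by 2.99, Spp2 by 2.97 and Azgp1 by 2.95; Cyp1a1 was at least 10.5-fold lower.

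Of 27 extracellular matrix genes, 18 rose in medulla at 120 h (19 adjusted over the list alone, with 1 lower), among them Cthrc1 (2.59), Col1a1 (2.53), Col3a1 (2.45) and Fn1 (2.15). Matrix genes passed camera with adjusted p = 7.38e-09, and adjusted p = 0.169 with an estimated correlation. Macrophage markers rose with 16 of 22 (20 adjusted over the list alone), such as Cd14 (2.44) and the mannose receptor Mrc1 (2.36). Macrophage markers passed camera with adjusted p = 3.87e-10, and adjusted p = 0.116 with an estimated correlation. Interferon genes had 13 of 20 members higher (14 adjusted over the list alone; adjusted p = 7.73e-08, and adjusted p = 0.116 with an estimated correlation). Complement genes had 9 of 16 higher (10 adjusted over the list alone; adjusted p = 1.15e-05, and adjusted p = 0.116 with an estimated correlation), and kidney injury genes 13 of 22 higher and 1 lower (15 and 2 adjusted over the list alone; adjusted p = 1.88e-07, and adjusted p = 0.116 with an estimated correlation). Acute phase genes without fibrinogen had 5 of 18 higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.00548, and adjusted p = 0.116 with an estimated correlation). Proximal tubule genes fell with 13 of 40 members (20 adjusted over the list alone), with a median of -1.27. Proximal tubule genes passed camera with adjusted p = 5.3e-10, and adjusted p = 0.248 with an estimated correlation. Distal tubule markers fell with 5 of 10 members (5 adjusted over the list alone), with a median of -0.78 and Klk1 at -3.25. Distal tubule markers passed camera with adjusted p = 0.00182, and adjusted p = 0.169 with an estimated correlation. Cell cycle genes had 13 of 35 higher and 1 lower (18 and 1 adjusted over the list alone), with a median of 0.65. Cell cycle genes passed camera with adjusted p = 1.52e-08, and adjusted p = 0.25 with an estimated correlation. MHC class II genes had 5 of 9 higher (7 adjusted over the list alone; adjusted p = 8.62e-06, and adjusted p = 0.0833 with an estimated correlation).

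In medulla at 120 h 2096 probes passed, 1106 higher and 990 lower (52.8% higher), and median scaling gave 1319 and 747 (63.8% higher). Without the library labelled sham medulla replicate 1 the count was 949, with 5 proximal tubule genes and 1 distal tubule marker lower and 13 matrix, 8 macrophage, 7 interferon, 7 complement, 11 cell cycle and 9 injury genes higher; it was 1005 and 1131 without 120 h medulla replicates 2 and 3, and 79 with the distal tubule covariate.

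**Figure D4:**
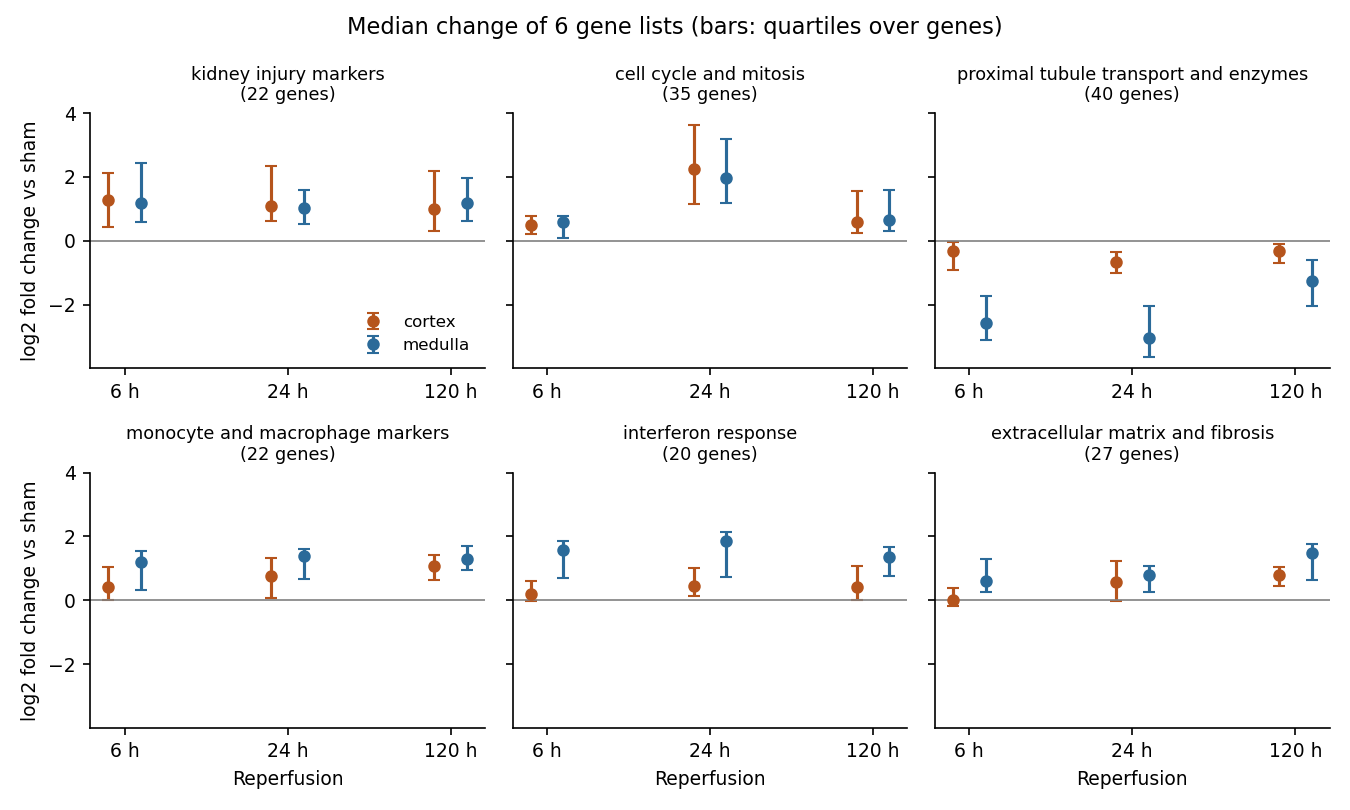
Median log2 change against sham (vertical axis) by reperfusion time (horizontal axis) in cortex and medulla (colour), with bars for the quartiles over genes. The panels show the kidney injury, cell cycle, proximal tubule, macrophage, interferon and extracellular matrix lists. The proximal tubule list has a median of -3.05 in medulla at 24 h and the cell cycle list one of 2.24 in cortex at 24 h.

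Many of the same probes changed in both regions, whose sham arrays were not shared. At 6 h 910 probes were higher in both (221 if the lists were independent) and 1135 lower in both (257). At 24 h the counts were 1328 (311) and 1239 (304), and at 120 h 265 (27.1) and 219 (31.7), and at 6 and 24 h 5 probes each were called in opposite directions. The regions share the same estimate of the spread per probe, so calls are not independent and the counts in parentheses may be too low. Changes correlated across probes with r = 0.729, 0.761 and 0.718, although probes are not independent replicates.

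A test of the difference between the regional responses called 29 probes at 6 h (15 higher and 14 lower in medulla), 8 at 24 h (3 and 5) and 2 at 120 h (1 and 1), against 1656, 1413 and 813 at an unadjusted p under 0.05. At 6 h the medulla response exceeded that of cortex for the tight junction gene Cldn1 by 2.90 ± 0.47, Art3 by 1.93 and the interferon-induced gene Ifit3 by 1.92. Cdhr1, Slurp1 and Hcrtr1 were called higher too, without a size, since at least 1 of the 4 groups was not above background. It was lower for Entpd5 (-2.28 ± 0.45), Sec16b (-2.23), the ectonucleotidase gene Nt5e (-2.14), the zinc transporter gene Slc39a5 (-2.03) and Wfdc1 (-1.995). At 24 h the medulla response of Hpx was lower than that of cortex, a difference of -2.91 ± 0.35 (adjusted p = 0.000667), and the response of Slc39a5 (-2.18) and Igsf11 (-2.04) was also lower in medulla. Spp1 was called at 24 and 120 h with fitted differences of -1.96 and -1.90 (adjusted p = 0.0108 and 0.0413; at 120 h 7.85e-05 to 0.465 over its alternatives), which do not show a smaller response in medulla. In medulla and cortex it lay 0.13 and 0.17 below the top of the normalized scale (14.775) at 24 h and 0.26 and 0.36 at 120 h, where levels are compressed, and sham medulla began 2.00 above sham cortex. The other call at 120 h was a probe without a gene name. The Spp1 call at 120 h ended without sham cortex or sham medulla replicates 2 or 3 or any one of the 6 arrays of that time, without a filter on dim probes, with 1 probe per gene, with only the groups compared and with the distal tubule covariate. With only the groups compared or that covariate the Spp1 call at 24 h ended as well (3.2e-05 to 0.103 over its alternatives), and with only the groups compared that of Hpx (3.53e-05 to 0.0608).

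The number of differing probes at 6 h was 10 without sham cortex replicate 2 or 3, 18 without the library labelled sham medulla replicate 1, 62 without sham medulla replicate 2, 18 and 15 without 6 h cortex replicates 1 and 3, and 62, 114 and 8 without 6 h medulla replicates 1, 2 and 3. At 24 h it was 54 without sham medulla replicate 2, 17 without 24 h cortex replicate 3, 140 and 5 without 24 h medulla replicates 1 and 2, and from 2 to 820 under other settings, and at 120 h 5 and 4 without sham medulla replicates 1 and 2 and 1 without sham cortex replicates 2 or 3 or any one of the 6 arrays of that time.

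Between 6 and 24 h mitotic genes rose in both regions. In cortex Cdk1 rose by 4.13 ± 0.37, Pbk by 3.77 ± 0.24, the cyclin Ccna2 by 3.69 ± 0.31, Rrm2 by 3.51 and Aurkb by 3.46, and 25 of 35 cell cycle genes rose (29 adjusted over the list alone, with 1 lower), with a median of 1.76, or 1.62 at the bounds and 1.12 with the series values. The list test passed with a preset and with an estimated correlation (adjusted p = 3.91e-55 and 0.00872). In medulla Rrm2 (3.44), Pbk (3.42), Aurkb (3.36), Pclaf (3.34) and Ccna2 (3.28) rose most, and 22 of 35 cell cycle genes rose (28 adjusted over the list alone; adjusted p = 2.29e-46, and adjusted p = 0.0197 with an estimated correlation). In cortex hemopexin Hpx was at least 7.42-fold higher at 24 h than at 6 h, and Clu (2.52), Serpina3n (2.29), Cfi (2.27), C4b (2.16), Lbp (1.68) and Spp1 (1.02) rose with the fibrinogen chains. Cldn22 (-1.85), the stress-induced gene Zfand2a (-1.78), Acp3 (-1.78), Maff (-1.63) and Gng7 (-1.59) fell in cortex, and the neutrophil gene S100a8 (-2.49), Abcb1b (-2.05), Acp3 (-1.70), Fgl2 (-1.69) and Krt20 (-1.55) fell in medulla. Limma called 216 probes in cortex (188 higher and 28 lower), where median scaling gave 274 and 9, and 201 in medulla (158 and 43, 78.6% higher), where median scaling gave 196 and 17 (92.0% higher). The medulla count was 105 without 24 h medulla replicate 3 and 0 by limma with only the groups compared (1517 at an unadjusted p under 0.05). Another split of the same medulla arrays gave 197.

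Between 24 and 120 h mitotic genes fell in both regions and proximal tubule genes rose in medulla. In cortex 23 of 35 cell cycle genes fell (32 adjusted over the list alone), with a median of -1.46 (adjusted p = 2.02e-36, and adjusted p = 0.0498 with an estimated correlation), and 3 of 9 MHC class II genes rose (6 adjusted over the list alone), such as RT1-Db1 (1.72) and Cd74 (1.09). MHC class II genes passed camera with adjusted p = 1.76e-05, and adjusted p = 0.0498 with an estimated correlation. Gatm rose there by 2.96 ± 0.62, Hpgd by 2.02, Cbx6 by 1.97, Gna12 by 1.79 and Apmap by 1.74, while Fam25a (-3.44), Cyp3a9 (-3.11) and Hpx (-2.76) fell with the fibrinogen chains. In medulla 11 of 40 proximal tubule genes rose (23 adjusted over the list alone), with a median of 1.56, among them Gatm (3.94 ± 0.62), Slc34a1 (3.00 ± 0.68), Cyp2e1 (2.90) and the urate transporter Slc22a12 (2.42). Proximal tubule genes passed camera with adjusted p = 7.7e-15, and adjusted p = 0.573 with an estimated correlation. Ugt2b35 (3.29), Cyp4a8 (2.93), Serpinf2 (2.53), F2 (2.24) and Mrc1 (1.78) rose there too. Medullary cell cycle genes fell with 20 of 35 members (29 adjusted over the list alone; adjusted p = 1.18e-22, and adjusted p = 0.301 with an estimated correlation), and Glycam1 (-3.21), Cyp3a9 (-2.74), the kinetochore genes Cenpk (-2.26), Kntc1 (-2.11) and Nuf2 (-2.11) fell most.

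Between 24 and 120 h 337 probes passed in cortex (128 higher and 209 lower) and 563 in medulla (283 and 280). The cortex count was 209 and 135 without 24 h cortex replicates 1 and 2 and 143 and 145 without 120 h cortex replicates 1 and 3, and the medulla count was 263 and 102 without 24 h medulla replicates 2 and 3 and 154 and 292 without 120 h medulla replicates 2 and 3.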

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

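The exchanges of arrays between regions, the distal tubule test, the distal tubule covariate and the standard-error requirement for the glomerular and platelet tests were chosen only after results were seen, as was reading undetected liver genes from probes below the filter. Some values behind the other tests, such as the similarity of 1 library to sham cortex and the proximal tubule rise in medulla, were also known when those tests were set.

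The test of the difference between regional responses singled out 29 probes at 6 h, 8 at 24 h and 2 at 120 h. At 6 h the medulla response was higher than that of cortex for Cdhr1 (3.12), Cldn1 (2.90), Slurp1 (2.53), Hcrtr1 (2.05), Art3 (1.93) and Ifit3 (1.92), and lower for Entpd5 (-2.28), Sec16b (-2.23), Nt5e (-2.14), Slc39a5 (-2.03) and Wfdc1 (-1.995), where the values of Cdhr1, Slurp1 and Hcrtr1 are fitted values and no sizes, since at least 1 of the 4 groups was not above background. At 24 h it was lower for Hpx (-2.91), Slc39a5 (-2.18) and Igsf11 (-2.04). Spp1 was called at 24 h (-1.96) and 120 h (-1.90), values that are no sizes of a difference in response, since its injured groups in both regions lay within 0.5 of the top of the normalized scale (14.775) and the sham regions differed by 2.00. Of 100 relabellings of the arrays, the real one included, 13, 12 and 11 gave at least as many probes at 6, 24 and 120 h, with 6199, 6391 and 3482 at most. Reversing the labels in 1 region adds the responses instead of subtracting them, so the highest of these counts point to the structure of the samples. Of 100 exchanges of arrays between the regions, 20, 12 and 17 gave at least as many probes, with 2551, 2477 and 2071 at most. Exchanging the regions in sham but not at that time, or the reverse, adds the differences between regions instead of subtracting them. Neither set of counts therefore decides whether chance accounts for the real ones, and chance was not excluded.

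Differences between regional responses were also called for 9, 10 and 9 of 33 lists at 6, 24 and 120 h, given here as median log2 differences, medulla minus cortex. At 6 h they were oxidative stress (-0.34), chemokines (0.68), macrophage (0.55), endothelial (0.62), proximal tubule (-2.19), distal tubule (-0.65), fatty acid oxidation (-0.41), extracellular matrix (0.84) and interferon genes (1.00). At 24 h they were fibrinogen (-2.50, a fitted value, since Fgb was not above background in sham medulla), oxidative stress (-0.39), macrophage (0.485), endothelial (0.53), proximal tubule (-2.31), distal tubule (-0.34), collecting duct (0.515), fatty acid oxidation (-0.145), interferon (0.77) and MHC class II genes (0.57). At 120 h they were endothelial (0.28), proximal tubule (-0.965), distal tubule (-0.41), fatty acid oxidation (-0.35), oxidative phosphorylation (-0.27), extracellular matrix (0.545), interferon (0.60), cholesterol (-0.19) and adipocyte genes (-1.56). With an estimated correlation the adjusted p ran from 0.178 to 0.757, 0.168 to 0.643 and 0.371 to 0.737, so all 28 of these camera calls were lost.

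The comparisons of 3 with 3 arrays allow 10 splits each, too few for a share under 0.05, and 1 of 10, the real one, reached the real count. The real and highest other counts were 2826 and 463, 3766 and 1, and 813 and 0 in cortex at 6, 24 and 120 h, 4870 and 15, 4708 and 1, and 2096 and 0 in medulla, and 200 and 185 between the sham regions. From 6 to 24 h they were 216 and 18 in cortex and 201 and 197 in medulla, and from 24 to 120 h 337 and 1, and 563 and 11.

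Proximal and distal convoluted tubule markers were lower in injured than in sham medulla. From 24 to 120 h in medulla proximal tubule genes rose by 1.246 more than distal tubule genes (medians 1.56 and 0.31). The permutation p was 0.00346 over genes, which are not independent. The rule for this test was set when that rise was already known. It counted such a difference against more cortex tissue in sham medulla as the whole cause of the proximal tubule fall. That step holds no sham array, so it cannot measure the tissue of sham medulla, and no conclusion is drawn from it. Nor was the tissue of the injured groups tested. Cortex genes lay at -2.67, -3.59 and -4.19 on the 24 h medulla arrays and at -2.03, -2.54 and -2.86 at 120 h. These genes were chosen as lower in injured medulla than in injured cortex. Low values on these arrays therefore follow from the choice and do not gauge their cortex tissue. For distal tubule genes more cortex tissue may account for the fall, with a median of -0.9735 over the 3 times in medulla against -0.175 in cortex. By time the medians were -0.638, -1.306 and -0.779 in medulla and 0.182, -0.447 and -0.228 in cortex at 6, 24 and 120 h. The cortex median was thus below 0 at 24 and 120 h, and no sham medulla array enters those values. Glomerular genes had a median difference of 0.1115 over 10 genes (standard error of the mean over genes 0.309), 4 below and 6 above 0. By the rule set beforehand that median argued against more cortex tissue. It lay above the bound by less than that standard error of the mean, a requirement added later, so these genes did not decide. The bound assumed members that follow cortex content, but they moved both ways, with Nphs1 lower. Tcf21 (0.08) and Plce1 (0.50) were not lower in sham medulla than in sham cortex. Loss of tubule transcripts through the injury itself, which the design names, was not tested apart from this and stays open.

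The library labelled sham medulla replicate 1 resembled sham cortex. A swap with a sham cortex library was argued against, since the highest sham cortex array lay at 0.2051 for medulla genes and the other sham medulla arrays at 1.72 and 2.00. A cortex sample with a wrong label may account for it, with 0.1429 for medulla genes, inside the sham cortex range of -0.137 to 0.205. A medulla sample with more cortex tissue cannot be told apart from this, because its cortex genes lay at -0.3448, below the sham cortex range of -0.090 to 0.104 and above the other sham medulla arrays (-1.96 and -1.15). A difference between animals was not tested and stays open.

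Fgb and Fgg were higher in cortex at 24 h. RNA from liver was argued against: 9 measured liver genes of 18 had a median change of 0.0492, and of 8 liver genes undetected in sham cortex, Alb (-0.01) and Ttr (0.09) among them, 0 were detected at 24 h. Of the 16 liver genes with a probe, 8 were detected on a sham cortex array, so kidney levels could hide a small share for those. RNA from platelets cannot be told apart with 3 measured genes of 10, whose median change was 0.4367, with Pf4 at 1.285 (limma adjusted p = 0.0487). That median lay under the bound of 0.5 set beforehand by less than the standard error of the mean over these genes. Ppbp (0.08), Gp5 (-0.05) and Treml1 (0.05), read from probes below the filter, lay near background. Expression by kidney cells after injury, which the design names, was not tested directly and stays open.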

How the results depend on the processing

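The distal tubule covariate and the list counts without the library labelled sham medulla replicate 1 were chosen after the data were seen; the other settings were chosen beforehand. Fgb in each of the 6 comparisons with sham kept its direction and its call under the settings chosen beforehand, each array left out included, and Fgg did so in cortex at 24 h. Of 799 results for named genes, 736 to 757 kept direction and call under the series values, median scaling, quantile normalization alone and normexp with an offset of 50. It was 798 with 1 probe per gene or animal as a random block, 789 with trend and robust settings, 773 with array weights, 708 without a filter, 705 at 2-fold or more, 561 with only the groups compared and 551 at an adjusted p under 0.01. It was 792 of 795 with the strict filter, 610 of 717 with only the 12 arrays of a region, 180 of 484 with the distal tubule covariate and 4148 of 5058 over single arrays left out, with 0 reversed there. Of 138 list calls by camera, 5 held with an estimated correlation, 77 with fry, 124 with the series values, 125 without a filter, 129 with quantile normalization alone, 58 of 95 with the covariate and 67 of 81 without the library labelled sham medulla replicate 1, and the medians of all 138 kept their sign under 4 other scalings. Setting genes with only a bound at that bound moved a list median by at most 0.289 (urothelium markers between the sham regions) and turned 1 sign, that of fibrinogen between the sham regions. Signal over background limited the low genes: Fgb and Fgg in sham lay near background, where background correction sets the size of a fold, bounds included. The slide as a block was not run, since no slide is given in the sources used here. The cause was not tested for any changed value below, except that fewer arrays, a stricter threshold or the covariate's larger standard errors call fewer probes.

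Counts of changed probes are given by setting, for 6, 24 and 120 h against sham. With a change of at least 2-fold they were 1309, 1909 and 504 in cortex and 2535, 2424 and 1120 in medulla, and from 24 to 120 h 220 in cortex and 347 in medulla. At an adjusted p under 0.01 they were 1352, 2172 and 286 in cortex and 3024, 2705 and 705 in medulla, 26 between the sham regions, 4, 4 and 1 for the difference between responses, 124 and 119 between times in cortex and 95 and 145 in medulla. With only the groups compared they were 805 in cortex at 6 h and 463 at 120 h, 1 and 2 for the difference between responses at 6 and 24 h, 107 from 6 to 24 h in cortex and 146 from 24 to 120 h in medulla. That setting gave 0 by limma between the sham regions, for the difference between responses at 120 h and from 6 to 24 h in medulla (1410, 954 and 1517 at an unadjusted p under 0.05). With only the 12 arrays of a region they were 513 in cortex at 120 h, 206 from 24 to 120 h in cortex, and 93 and 361 between times in medulla. With array weights they were 1888 in cortex and 3610 in medulla at 120 h, 2131 between the sham regions, 68, 820 and 16 for the difference between responses, 1997 from 24 to 120 h in cortex, and 675 and 2767 between times in medulla. With the distal tubule covariate they were 736, 86 and 79 in medulla, 575 between the sham regions, 4 for the difference between responses at 6 h and 209 from 24 to 120 h in medulla. Without a filter on dim probes 118 differed between the sham regions.

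The difference between responses at 6 h gave 9 probes with quantile normalization alone, 9 with normexp at an offset of 50, 12 with the series values, 16 with median scaling and 13 without a filter. At 24 h it gave 5 with the series values, 13 with median scaling, 37 with the strict filter, 33 with 1 probe per gene, 38 with animal as a random block and 40 with trend and robust settings. At 120 h it gave 1 without a filter, 4 with trend and robust settings and 0 by limma with 1 probe per gene (576 at an unadjusted p under 0.05). Replicate numbers were not taken to pair the samples in the main fit. All pairs correlated above 0.1 in 1 of 4 comparisons of cortex with medulla at the same time (24 h, r from 0.262 to 0.398, a hint of pairing there), against r from -0.174 to -0.017 in sham. They did so in 1 of 12 comparisons between times and 1 of 12 others. With a replicate block the difference between responses gave 38 probes at 24 h and 1 at 120 h, no other count moved by over 1.5 times, and 785 of 799 named gene results and 135 of 138 list calls stayed.

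Fgg lost its call in cortex at 120 h at an adjusted p under 0.01, with only the groups compared, with only the 12 arrays and without a filter (2.39 each), with quantile normalization alone (1.51), normexp at an offset of 50 (1.52) and the series values (1.20). In medulla it did so under quantile normalization alone (1.31 at 6 h and 1.42 at 120 h), normexp at an offset of 50 (1.31 and 1.43), the series values (1.03, 1.19 and 1.11 at 6, 24 and 120 h) and an adjusted p under 0.01 (2.11 at 6 h and 2.31 at 120 h). With the distal tubule covariate the medulla differences of Fgb (2.84, 3.23 and 3.43) and Fgg (2.05, 2.36 and 2.25) did not pass, those of Fgb and of F13b being fitted values and no sizes, since 1 group was not above background. Klk1 at 6 h turned to 0.249 with that covariate, and at 24 h Serpinc1 to 0.457, F13b to 0.430, Slc12a3 to 0.305, Maff to 0.483 and Clic5 to 0.244. At 120 h Apcs turned to 0.715 and Slc12a3 to 0.240, none of these passed, and Klk1 and Slc12a3 belong to the list behind the covariate. Standard errors rose with the covariate by a median of 1.49, 1.76 and 1.501 times over probes at 6, 24 and 120 h, which lowers counts by itself.

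Leaving out 1 array at a time, the counts ranged from 1253 to 3950, 2545 to 3336 and 297 to 676 in cortex and from 3605 to 4612, 3160 to 4570 and 949 to 1737 in medulla. They ranged from 21 to 798 between the sham regions, from 8 to 114, 5 to 140 and 1 to 5 for the difference between responses, from 145 to 274 and 135 to 232 between times in cortex and from 105 to 240 and 102 to 818 in medulla. The Fgg difference ranged from 1.41 to 2.30 in cortex at 6 h, 1.82 to 3.05 in cortex at 120 h, 1.525 to 2.66 in medulla at 6 h and 1.95 to 2.63 in medulla at 120 h.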

Other observations

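The lists below were tested as planned, and none of these tests was chosen after the result was seen.

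Of 36 oxidative phosphorylation genes 5 fell in medulla at 24 h (5 adjusted over the list alone), led by Ndufb8 (-1.32) and Sdha (-0.84), and the list passed camera (adjusted p = 0.0159, and adjusted p = 0.727 with an estimated correlation). At 120 h it passed as well, with a median of -0.22 (adjusted p = 0.00124, and adjusted p = 0.546 with an estimated correlation) and 1 member lower, Uqcrfs1 (-0.48), which missed the threshold when adjusted over the list alone. In sham medulla the list was higher than in sham cortex, with a median of 0.233 (adjusted p = 0.000991, and adjusted p = 0.635 with an estimated correlation). Glycolysis and hypoxia genes moved both ways in medulla at 6 h, with 6 of 19 higher and 2 lower (7 and 2 adjusted over the list alone), such as the lactate exporter gene Slc16a3 (1.99) and the angiogenic factor gene Vegfa (-1.52), and the list did not pass (adjusted p = 0.37). Cholesterol synthesis genes had 5 of 13 higher in cortex at 24 h (6 adjusted over the list alone), led by Sqle (1.53) and Idi1 (1.27), without a list call (adjusted p = 0.0753). Heat shock genes had 4 of 14 higher in cortex at 6 h (4 adjusted over the list alone), with Cryab (3.05) and Hspb1 (2.37) highest and an adjusted p of 0.0658. Of 14 p53 targets 1 rose in cortex at 6 h (1 adjusted over the list alone), Phlda3 (1.48), with an adjusted p of 0.283.

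Lymphocyte markers rose in medulla at 120 h with 6 of 16 members (9 adjusted over the list alone), led by Lck (1.58) and Cd8a (1.44); adjusted p = 2.45e-05, and adjusted p = 0.185 with an estimated correlation. Endothelial markers moved both ways in medulla at 6 h, with 5 of 17 higher and 2 lower (7 and 2 adjusted over the list alone), Esam (1.69) and Vwf (-1.91) among them, and an adjusted p of 0.482. Collecting duct markers did so as well, with 6 of 24 higher and 3 lower (7 and 3 adjusted over the list alone), such as Fxyd4 (2.58) and the intercalated cell gene Slc26a4 (-2.82), and an adjusted p of 0.851. Of 7 erythrocyte markers 2 rose in medulla at 6 h (2 adjusted over the list alone), Ahsp (1.29) and Bpgm (0.89), with an adjusted p of 0.157. Of 6 adrenal markers 2 were higher and 1 lower there (2 and 1 adjusted over the list alone), Hsd3b1 (1.69), Dbh (0.96) and Cyp21a1 (-0.70), with an adjusted p of 0.471. The 4 urothelium markers had a median of 0.605, or 0.316 with 2 genes at their bound, in sham medulla against sham cortex (3 higher adjusted over the list alone), with a camera adjusted p of 0.0106, and adjusted p = 0.423 with an estimated correlation.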
